A study of Mus musculus with 12 samples.

How the data were processed

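Gene expression was measured in whole eyes of WT and cKO mice, with 12 libraries in all, 6 per genotype and 1 per genotype and circadian time. The RNA of 3 mice was pooled in equal amounts before each library, per the labels, so 18 mice stand behind each genotype and the spread between single mice was not measured. The values are counts per gene as deposited, in a sheet that the authors call raw data. They were whole numbers with no sign of scaling or log transformation. The aligner, the counting tool, the genome build, the annotation and whether reads were subsampled to a common number are not given in the sources used here. Totals per library ran from 10466253 to 10686868, a spread of 2.11%.

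The deposited table held 32544 gene entries. Of these, 27 were left out because a spreadsheet had turned their gene names into dates (25 distinct dates, so that some names could not be told from each other). They held a median of 0.158% of the counts per library. Of the 32517 entries kept, 21987 had a count in some library, and 15134 passed the filter of edgeR (filterByExpr by genotype, minimum count 10, minimum total count 15) and were tested. Counts were normalised by TMM in edgeR 4.0.16 under R 4.3.3. CPM values are counts scaled by the TMM library size in the usual way, and log2 CPM used a prior count of 2. The coefficient of variation between pools that edgeR estimated was 6.1%.

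Genotype was tested by the edgeR quasi-likelihood F test with circadian time as a factor (5 residual degrees of freedom), coded as cKO minus WT. Rhythms were tested in edgeR with cosine and sine terms of a 24 h period fitted within each genotype in 1 model of all 12 libraries (6 residual degrees of freedom), giving a test for WT, a test for cKO and a test of the difference of their terms. A model with terms common to both genotypes gave the shared test (8 residual degrees of freedom). Amplitude is the log2 distance from mean to peak, the fold range is peak over trough, and the SE of each estimate is the one implied by its F statistic. All p-values of these tests were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The amplitude ratio is the median over the genes past the shared test of the log2 ratio of the cKO to the WT amplitude, tested exactly over the 32 within-time swaps of genotype.

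Lists for 27 gene groups were fixed before the data were examined: core clock, clock output, glucocorticoid targets, corticosteroid receptors and enzymes, rods, cones, bipolar cells, amacrine and horizontal cells, ganglion cells, Müller glia, reactive glia, pigment epithelium, ciliary body, aqueous humour, lens, cornea and conjunctiva, stroma and sclera, extraocular muscle, red blood cells, immune cells, vessels, immediate early genes, heat shock, cholesterol synthesis, mitochondrially encoded genes, nuclear oxidative phosphorylation and ribosomal proteins. Each list was tested for genotype by camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one, and for shared rhythm calls by Fisher's exact test against all other tested genes. Member genes were also adjusted over their list alone. A score per library, the mean of log2 CPM centred per gene, was tested by exact permutation within times (64 sign assignments) or over the 720 orders of the times. These p-values were adjusted over lists.

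The genes to name were set by rule beforehand: Nr3c1 first, the 12 genes with the largest change in each direction past the genotype test, the 12 with the largest amplitude past each rhythm test, and the 10 with the smallest p for the rhythm difference, all with an average log2 CPM of at least 0 and an established name. Up to 4 members per list past a test by smallest p, and any member of the core clock and glucocorticoid target lists, could be named too. Other features named were picked after their values were seen.

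Alternatives chosen beforehand were DESeq2 size factors, no filter on low counts, limma-trend, DESeq2 1.42.0 in place of edgeR, leaving out both libraries of each time in turn, no time term or a cosine and sine in its place, each genotype fitted alone, and an added 12 h term. Alternatives added after the data were seen were a test for any difference between times, leaving out the WT library of CT18 or of CT22, leaving out the genes of the span on chromosome 3, the glucocorticoid target list for the amplitude ratio, the gene set test with DESeq2 size factors and with each time left out, and the rhythm difference with time as a factor (3 residual degrees of freedom). Each count of calls was also repeated over other splits of the libraries. Gene positions came from GENCODE M21 (GRCm38) by symbol, which placed 97.2% of the tested genes, although the build the authors used is not given.

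The code was tested on simulated data with known changes. The changed genes were drawn only from the better expressed of the tested genes, so recovery at low expression was not measured. Of 100 genes changed by genotype, 64 were recovered at a log2 change of 0.3 and 93 at 0.6, with 17 others called among 15055 genes. Of 100 genes with a rhythm in both genotypes, the shared test recovered 73 at an amplitude of 0.25 and all 100 at 0.5, the WT test 31 and 93, and the cKO test 40 and 93. With a rhythm in WT alone and no shared rhythm in any gene, the difference test recovered 3 and 56 and the shared test none. The difference test called 12 unchanged genes as well. With a rhythm in both genotypes, the shared test called 11 unchanged genes, the WT test 11 and the cKO test 7. With a rhythm in WT alone, the WT test recovered 36 and 84 and called 13 unchanged genes. In the genotype, difference and WT rhythm tests the unchanged genes were a larger share of the calls than the threshold of 0.05 aims at. In the shared test that share was slightly above it. Among unchanged genes, 4.53% to 5.04% had an unadjusted p below 0.05. In the real data 2.58% of all genes did so in the difference test, so recovery by that test may differ from the simulated one. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.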

Results

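Gene expression was measured by RNA sequencing of whole eyes from male mice aged 12 weeks that carried either an intact gene for the glucocorticoid receptor, Nr3c1 (Cre-negative, called WT here), or a retina-specific deletion of it (Cre-positive, called cKO). The mice were kept in 12 h of light and 12 h of dark for 2 weeks and then moved to constant darkness, and eyes were taken on day 2 of darkness at circadian times (CT) 2, 6, 10, 14, 18 and 22, at intervals of 4 h. Equal amounts of RNA from 3 mice were pooled into each library, which gave 12 libraries, 6 per genotype, with 1 library for each genotype and time. The protocols and the study design name whole eyes as the source, the series title names the retina, and the sample characteristics name the ciliary body and a nonpigmented ciliary epithelial cell line. Whole eyes are taken as the source here, since genes of the lens, cornea, muscle and photoreceptors were all expressed. Totals per library ran from 10466253 to 10686868 counts, and 15134 genes were tested. The comparisons asked what differed between genotypes at all times of day, which transcripts varied with circadian time, and whether that variation differed between genotypes.

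Nr3c1 itself was lower in cKO in each of the 6 pairs of libraries from the same time. Its normalised level in WT was 71.8 CPM at CT2, 65.9 at CT6, 55.4 at CT10, 76.1 at CT14, 65.3 at CT18 and 60.6 at CT22. In cKO it was 38.8, 49.3, 42.9, 49.3, 45.0 and 49.6 CPM at the same times. The group means were 65.8 CPM in WT and 45.8 CPM in cKO (n = 6 each), a log2 difference of -0.52 ± 0.06 (SE, adjusted p = 0.0018). The counts cover the whole gene and the deleted exons are not given in the sources used here, so the remaining reads do not measure how complete the deletion was. Whole eyes also hold tissue outside the retina, where a retina-specific deletion would leave the gene intact. The difference is therefore not that of the retina alone. The mineralocorticoid receptor Nr3c2, which binds the same steroids, stood at 25.4 CPM in WT and 25.7 CPM in cKO, and the receptor cochaperone Fkbp4 at 192 and 197 CPM. Neither passed the test.

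Few genes differed between genotypes across the day: 21 genes passed the genotype test, 10 higher and 11 lower in cKO. All cKO mice were Cre-positive and all WT mice Cre-negative, so receptor loss cannot be told here from anything else that came with Cre. The largest decrease among named genes was that of Etnppl, an enzyme that breaks down phosphoethanolamine, from a mean of 13.1 to 5.08 CPM (log2 difference -1.37 ± 0.15 SE, adjusted p = 0.000629), lower in all 6 pairs. Gpx3, the secreted glutathione peroxidase, fell from 352 to 219 CPM (-0.71 ± 0.09, adjusted p = 0.00435), also in all 6 pairs. Folh1, a carboxypeptidase that releases glutamate from small peptides, fell by 0.68 on the log2 scale, Hdc, the enzyme that makes histamine, by 0.55, and Fam107a, an actin-binding protein known to be induced by glucocorticoids, by 0.31. Each of these was lower in all 6 pairs. The pituitary hormone transcript Gh was lower as well (5.70 to 2.24 CPM, -1.30 ± 0.23, 5 of 6 pairs), at only 19 to 86 counts per library. Among higher genes, Krt13, a keratin of mucosal epithelium such as the conjunctiva, rose from 292 to 378 CPM (0.37 ± 0.06, adjusted p = 0.0228), and Plet1, a surface protein of epithelial progenitors, from 144 to 181 CPM (0.34 ± 0.05). Plac8 (0.30 ± 0.05) and Abcd4, a lysosomal transporter needed for vitamin B12 use (0.39 ± 0.07), were also higher in all 6 pairs.

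**Figure D1:**
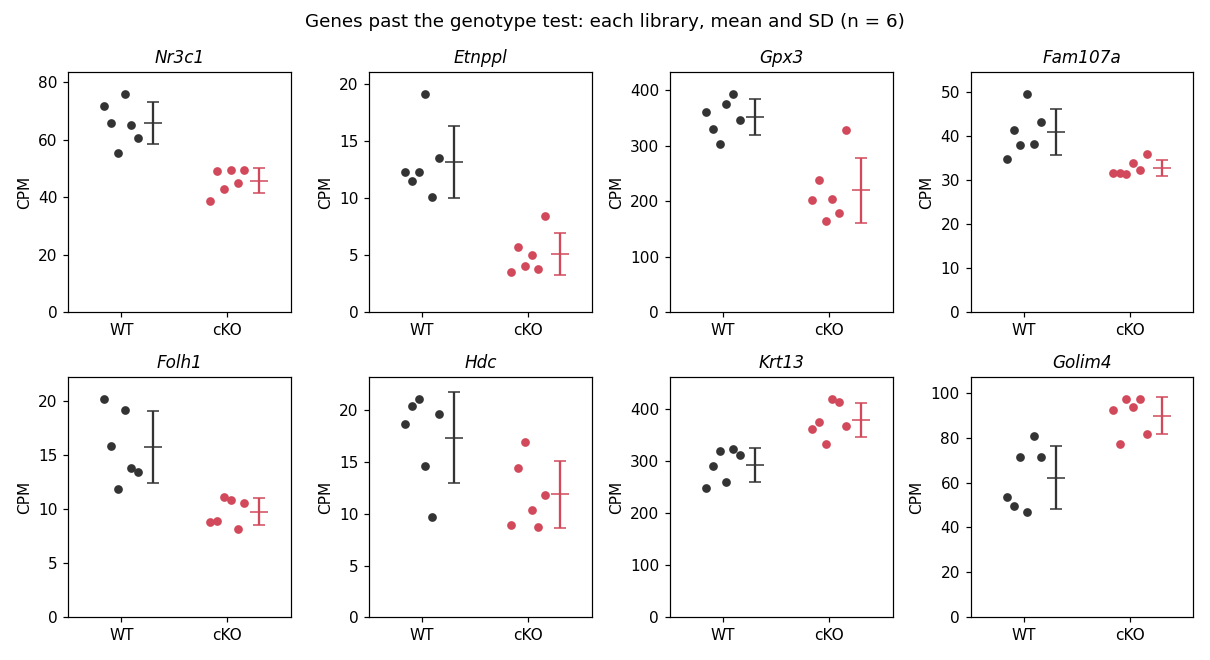
Expression in CPM (vertical axis, from 0) of 8 genes past the genotype test, with 1 point per library ordered from CT2 to CT22 within each genotype, and the mean and SD (n = 6) beside the points. Nr3c1 lay between 55.4 and 76.1 CPM in WT and between 38.8 and 49.6 CPM in cKO, and Etnppl, Gpx3, Fam107a, Folh1 and Hdc had lower means in cKO while Krt13 and Golim4 had higher means.

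The remaining 6 higher genes lay together on chromosome 3: Schip1 (log2 difference 0.48 ± 0.09 SE), Ift80 (0.33 ± 0.05), Kpna4 (0.38 ± 0.06), Ppm1l (0.33 ± 0.06), Serpini1 (0.31 ± 0.05) and Golim4 (0.55 ± 0.08, adjusted p = 0.0101). These encode, in that order, a cytoskeletal adaptor of axons, a component of ciliary transport, an importin, a protein phosphatase, the protease inhibitor neuroserpin and a Golgi membrane protein. By gene symbol in GENCODE M21 (GRCm38), the span runs from position 68064802, the start of Schip1, to 75956949, the end of Golim4. Of the other 10 genes tested in it, 9 were also higher in cKO without passing the test, with a median log2 difference of 0.33 over the 10. The 10 tested genes before the span had a median of -0.06 and the 10 after it 0.01. Of the 11 lower calls, 4 were gene models outside the naming rule, singled out after their values were seen: the pseudogenes Rps13-ps1 (log2 difference -5.03), Rps2-ps10 (-1.64) and Gm10146 (-2.20), and 6820431F20Rik (-0.37). Rps13-ps1 had between 954 and 1142 counts in WT at CT2 to CT14, none at CT18 and 55 at CT22. In cKO it had 136 at CT2 and none at the other times. Rps2-ps10 had 279 to 524 counts in WT at CT2 to CT14, 88 at CT18 and 81 at CT22, and 73 to 107 in cKO. The mean score of the chromosome 3 span was likewise nearer to cKO (0.09 to 0.28) in WT at CT18 (0.02) and CT22 (-0.01) than at the earlier WT times (-0.36 to -0.12). The count of 21 fell to 5 without the CT2 pair of libraries, to 6 without the CT6 pair, to 12 without the CT10 pair and to 3 without the time term (1 higher and 2 lower), with 1 higher and 4 lower without CT2, all 6 lower without CT6, and 4 higher and 8 lower without CT10. Without the CT14 pair 6 were higher and 19 lower. Of the named genes Nr3c1 and Etnppl alone passed in all 13 alternatives that were run. Gpx3 passed in 12 of the 13, Krt13 and Plet1 in 10, Folh1 and Plac8 in 8, Gh, Hdc and Abcd4 in 6 and Fam107a in 5, and the 6 genes on chromosome 3 in 6 to 8 of the 12 that tested them. Among 100 simulated genes changed by 0.3 on the log2 scale 64 were recovered, and 93 of 100 changed by 0.6, so changes of the smaller size were missed in part. The same simulation called 17 unchanged genes.

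**Figure D2:**
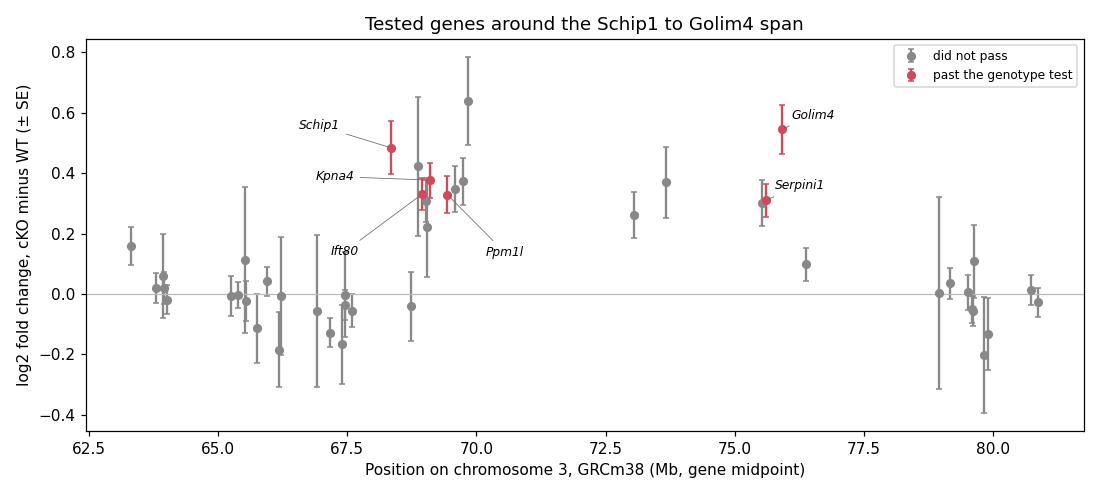
The log2 difference between genotypes (cKO minus WT, vertical axis, bars ± SE) of each tested gene against the midpoint of the gene on chromosome 3 in GRCm38 (Mb, horizontal axis), with genes past the test in red. Of 16 genes tested between Schip1 and Golim4, 15 lay above 0, whereas the flanking genes scattered around it.

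Of 29 glucocorticoid target genes, a list fixed before the data were examined, 20 were lower and 9 higher in cKO, with a median log2 difference of -0.07, and -0.04 without the CT10 pair of libraries (camera adjusted p = 0.00535). Fam107a alone passed, over all genes and adjusted over the list alone, and 7 members were lower at an unadjusted p below 0.05. Well-known targets that did not pass included Fkbp5 (30.4 CPM in WT and 28.5 in cKO), Tsc22d3 (52.4 and 48.4), Sgk1 (398 and 400), Hif3a (-0.42 ± 0.14 on the log2 scale) and Arrdc2 (-0.35 ± 0.11). These values include tissue outside the retina, so a change confined to the retina would be diluted in them. As a set the list was lower by camera with a preset correlation of 0.01 (adjusted p = 6.92e-05), and this was lost with a correlation estimated from the data (adjusted p = 0.343 with an estimated correlation). The same held for the 13 of 27 lists that camera called in all, of which 5 were higher and 8 lower in cKO: none was called with an estimated correlation, where the smallest adjusted p was 0.271 and 3 lists had an unadjusted p below 0.05.

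Whole eyes hold several tissues besides the retina, and lists of their markers, fixed before the data were examined, were compared between genotypes. Members named here and in the next paragraph that did not pass over all genes were picked after their values were seen. All 23 lens genes were higher in cKO, with a median log2 difference of 0.16. None passed over all genes, 15 passed adjusted over the list alone and 17 had an unadjusted p below 0.05 (camera adjusted p = 4.16e-22, and 0.322 with an estimated correlation). Their mean score in WT at CT22 was -1.15, against -0.14 to 0.23 in the other WT libraries, and without the CT22 pair the median was 0.12. Among 10 cone genes 9 were higher, none passing over all genes and 3 adjusted over the list alone. Opn1sw, the short-wave cone opsin, stood at 313 CPM in WT and 354 in cKO (median of the list 0.10, camera adjusted p = 6.48e-05, and 0.322 with an estimated correlation). Of 18 rod genes 16 were higher, with Sag, rod arrestin, at 3049 and 3748 CPM (adjusted p = 0.0978) passing only adjusted over the list alone (list median 0.04, camera adjusted p = 0.00776, and 0.64 with an estimated correlation). The rod median ran from 0.02 without the CT10 pair (adjusted p = 0.11) to 0.09 without the CT14 pair. The 12 corneal and conjunctival genes had a median near 0 (camera adjusted p = 0.00891, and 0.64 with an estimated correlation), with Krt13 past the test and Krt4 at 0.39 ± 0.09 past it adjusted over the list alone. Stroma and sclera genes were lower in all 10 cases (median -0.09, camera adjusted p = 0.0011, and 0.535 with an estimated correlation), with Dcn, the matrix proteoglycan decorin, at 486 and 379 CPM. Their score in WT at CT18 was 0.63, against -0.31 to 0.29 in the other WT libraries, 3 of 6 pairs were higher in cKO, and the median ran from -0.26 without the CT14 pair (camera adjusted p = 1.11e-13) to 0.02 without the CT18 pair (adjusted p = 0.668). Of 16 extraocular muscle genes 14 were lower (median -0.08, camera adjusted p = 0.0011, and 0.436 with an estimated correlation), and without the CT10 pair the median was -0.05 (adjusted p = 0.11). Retinal ganglion cell genes were lower in 10 of 11 cases, with Sncg at 44.9 and 39.8 CPM past the test adjusted over the list alone (list camera adjusted p = 0.0209, and 0.48 with an estimated correlation).

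The remaining lists covered cell functions and other cell types. Of 82 ribosomal protein genes 67 were lower (median -0.04, camera adjusted p = 6.48e-05, and 0.481 with an estimated correlation), as were 10 of 13 mitochondrially encoded genes (median -0.06, camera adjusted p = 0.00426, and 0.436 with an estimated correlation). Among 13 immediate early genes 9 were lower and none passed over all genes, while Fos (20.4 and 16.5 CPM) and Egr1 (40.4 and 28.9 CPM) passed adjusted over the list alone (camera adjusted p = 0.0209, and 0.436 with an estimated correlation). Cholesterol synthesis genes were higher in 16 of 20 cases (median 0.04, and 0.06 without the CT6 pair, camera adjusted p = 0.0209, and 0.48 with an estimated correlation). The 4 tested corticosteroid receptors and enzymes include the deleted gene itself, so the call of that list (camera adjusted p = 0.000204, and 0.271 with an estimated correlation) is not read as a change of the group. Of the 4, 2 were lower, Nr3c1 and Hsd11b1, which regenerates active corticosterone from its inert form (3.1 and 2.3 CPM, not past the test), and 2 were higher. Core clock, clock output, bipolar cell, amacrine and horizontal cell, Müller glia, reactive glia, pigment epithelium, ciliary body, aqueous humour, red blood cell, immune, vascular, heat shock and nuclear oxidative phosphorylation lists were not called by camera, the smallest adjusted p among them being 0.0667, although 1 aqueous humour gene passed the gene test adjusted over the list alone, lower in cKO. The red blood cell median was -0.31, and 0.06 without the CT18 pair. Over 7 alternatives of scaling or left-out pairs, camera with the preset correlation called the lens, cone, ribosomal, glucocorticoid target and corticosteroid receptor lists in all 7, muscle in 6, stroma, cornea, cholesterol synthesis and mitochondrially encoded genes in 5, and rods, ganglion cells and immediate early genes in 3. Of the lists not called above, red blood cells were called in 3 of the 7, without the CT2, the CT6 or the CT10 pair, and the aqueous humour, bipolar cell, heat shock, immune, nuclear oxidative phosphorylation, pigment epithelium and vascular lists in 1 each. The corneal median ran from -0.08 without the CT14 pair (adjusted p = 0.35) to 0.09 without the CT6 pair (0.00021), and the ganglion cell median -0.01 without the CT2 pair (adjusted p = 0.209). For clock output, Müller glia, reactive glia, pigment epithelium and vascular genes the median, mean and camera direction differed in sign. Scores per library, tested by the 64 exact assignments of genotype within times, gave no list past the adjusted threshold (smallest adjusted p = 0.527, with 1 list at an unadjusted p below 0.05, the smallest p possible being 0.0312).

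Circadian time had a broader footprint than genotype. In the model with a 24 h rhythm common to both genotypes, 523 genes passed, with a median peak-to-trough ratio of 1.35. Peaks clustered at opposite phases: 189 genes peaked around CT 18 and 122 around CT 6, against 42 to 74 in each of the other 4-h bins. The core clock was prominent, with 11 of 20 members past the test over all genes and 15 adjusted over the list alone (Fisher's exact test against the other tested genes, adjusted p = 1.29e-10). Dbp, a clock-driven transcription factor, peaked at CT 10.4 with a 1.62-fold range (amplitude 0.35 ± 0.03 SE on the log2 scale, taken as the distance from mean to peak, adjusted p = 3.32e-05). The repressors Per1 (1.54-fold, CT 13.3), Per2 (1.59-fold, CT 14.3) and Nr1d2 (1.30-fold, CT 14.8) followed in the early subjective night, and Ciart (1.95-fold) peaked earlier, at CT 9.3. Tef (CT 13.6) and Bhlhe41 (CT 14.2) also passed. Npas2, a partner of BMAL1, peaked at CT 2.7 with a 2.17-fold range, nearly opposite to Per1. Nfil3 (CT 19.2) and Rorb (CT 18.0) passed in the late night. Arntl, which encodes BMAL1, varied 1.15-fold with a fitted peak at CT 0.8 and did not pass (adjusted p = 0.268). Neither did Clock (adjusted p = 0.0566), Nr1d1 (0.055), Per3 (0.0748), Bhlhe40, Cry1, Cry2, Rora or Hlf.

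Genes known as outputs of the clock were tested in the same model. Of 15 clock output genes 6 passed over all genes, against 2 in WT and 2 in cKO by the tests within a genotype, and 8 adjusted over the list alone (Fisher's exact test, adjusted p = 4.29e-05). Drd4, the dopamine receptor of photoreceptors, peaked at CT 17.7 with a 2.09-fold range (adjusted p = 4.59e-05). In WT it went from 132 CPM at CT6 to 258 at CT14, and in cKO from 122 at CT6 to 231 at CT22. The cold-inducible RNA-binding protein Rbm3 (1.64-fold, CT 9.1, adjusted p = 2.19e-06) and the adenylyl cyclase Adcy1 (1.37-fold, CT 8.7) peaked in the subjective day, and the monooxygenase Fmo2 at CT 18.2 (2.20-fold). Arr3, cone arrestin, was among the most certain rhythms (1.84-fold, CT 10.9, adjusted p = 1.33e-06), and Irf7, a regulator of interferon genes, was the most certain of all (2.87-fold, CT 18.0, adjusted p = 1.28e-07). Among rod genes 4 of 18 passed and 5 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00989): Sag, Guca1b and Reep6 near CT 7.1, and the transcription factor Nr2e3 at CT 2.8 (1.67-fold).

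**Figure D3:**
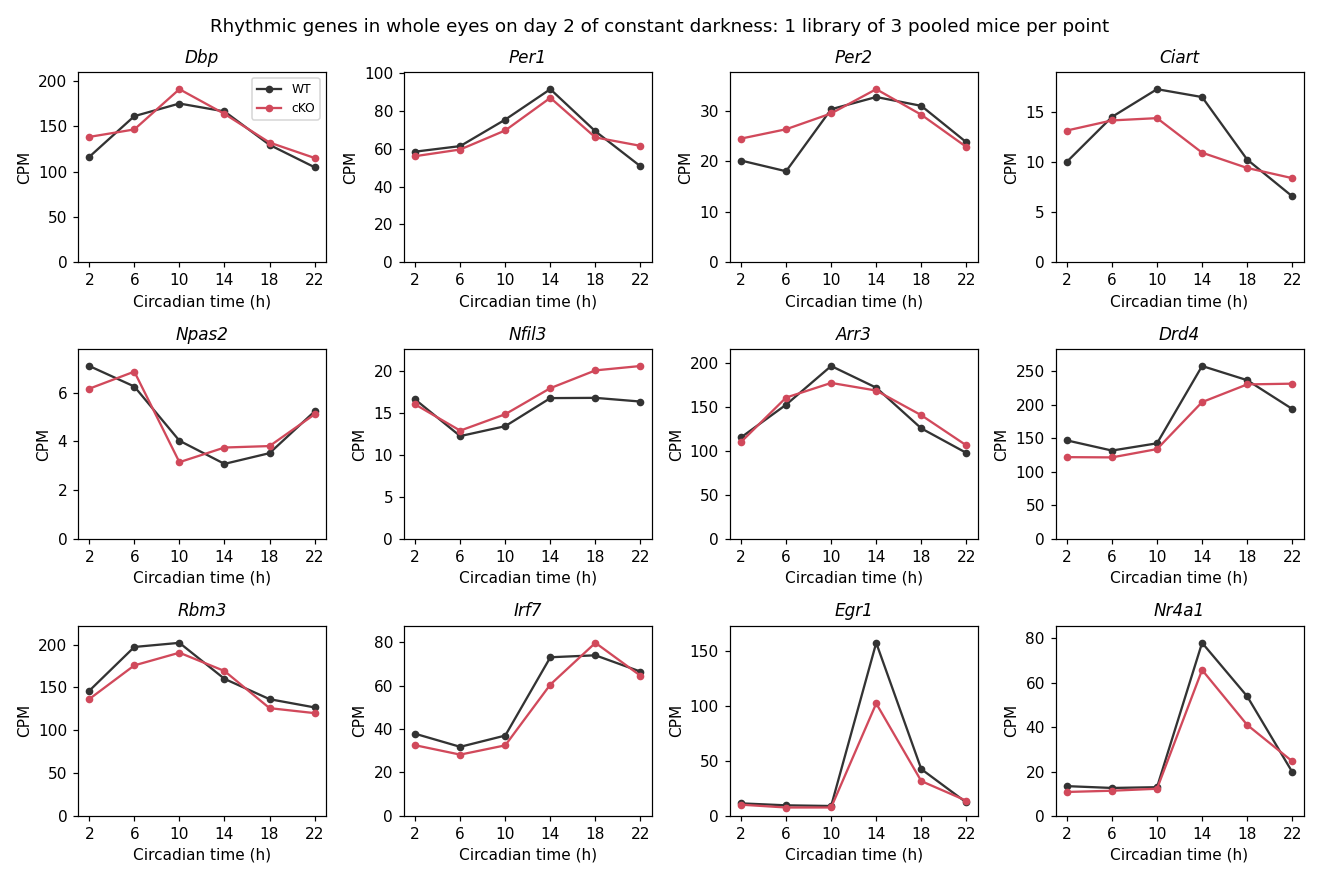
Expression in CPM (vertical axis, from 0) against circadian time in h (horizontal axis) of 12 genes past the shared rhythm test, in WT (black) and cKO (red), with 1 library of 3 pooled mice per point and therefore no error bars. Dbp, Arr3 and Rbm3 were highest at CT10 in both genotypes, and Egr1 and Nr4a1 were highest at CT14.

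The 2 largest amplitudes among named genes were those of Egr1 and Nr4a1, immediate early genes, which respond within minutes to neuronal or growth factor signals. Egr1 was at 157 CPM in WT and 102 CPM in cKO at CT14, against 7.63 to 13.8 CPM at CT2, CT6, CT10 and CT22 in both genotypes, and 42.6 and 31.7 CPM at CT18. Nr4a1 (fitted 7.25-fold, peak CT 16.1), Fos (4.21-fold, CT 15.7) and Nr4a3 (3.78-fold, CT 17.3) peaked in the same part of the night, and 5 of 13 members passed over all genes, 8 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000222). Without the CT14 pair the amplitude was 1.08 in place of 2.04 for Egr1 and 0.64 in place of 1.04 for Fos, both still past the test. Heat shock genes had a mean peak at CT 17.7, with 5 of 11 past the test over all genes and 8 over the list alone (adjusted p = 0.000102), among them the chaperones Hspa8 (1.36-fold, CT 17.8), Hspa1a (1.32-fold, CT 15.5) and Hsp90aa1 (1.34-fold, CT 19.1). Cholesterol synthesis genes peaked in the early subjective day, with 11 of 20 past the test and 16 adjusted over the list alone (adjusted p = 1.29e-10) at a mean peak of CT 3.9. They included Idi1 (1.36-fold, CT 2.6), Fdps (1.31-fold, CT 5.1) and Lss (1.28-fold, CT 5.1), enzymes of the pathway.

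Glucocorticoid targets were rhythmic across the genotypes in 8 of 29 cases over all genes and 15 adjusted over the list alone (Fisher's exact test, adjusted p = 3.92e-05), with a mean peak at CT 15.8. Tsc22d3, the glucocorticoid-induced leucine zipper (1.48-fold, CT 15.3), Sgk1 (1.24-fold, CT 17.1), Ddit4 (1.51-fold, CT 16.0), Irs2 (1.28-fold, CT 13.2), Sult1a1 (1.64-fold, CT 14.9), Mt2 (1.33-fold, CT 21.0), Cdkn1a (1.43-fold, CT 2.9) and Per1, which is also a core clock gene, passed. Of 17 aqueous humour genes 4 passed and 5 over the list alone (adjusted p = 0.00903). Angptl7, secreted by the trabecular meshwork and cornea, varied 5.15-fold (CT 16.2), the water channel Aqp1 1.61-fold (CT 17.0), the carbonic anhydrase Car3 1.88-fold (CT 10.7) and the adrenergic receptor Adra2a 1.43-fold (CT 13.5). The score of this list was highest in WT at CT18 (0.32) and in cKO at CT14 (0.24), the libraries where the stroma and sclera score was also highest (0.63 and 0.37), so a varying share of other tissue in these rhythms is not ruled out. Further leading genes by amplitude were Krt16 (5.29-fold, CT 0.1), a keratin of stressed epithelium, Ush1c (3.74-fold, CT 4.7), Slc46a2 (3.53-fold, CT 5.5), Col19a1 (3.37-fold, CT 6.1), Ndc80 (3.28-fold, CT 2.0) and the growth factor Epgn (3.18-fold, CT 20.5). Ndc80 kept its call in 1 of the 4 left-out pairs in which it was tested.

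**Figure D4:**
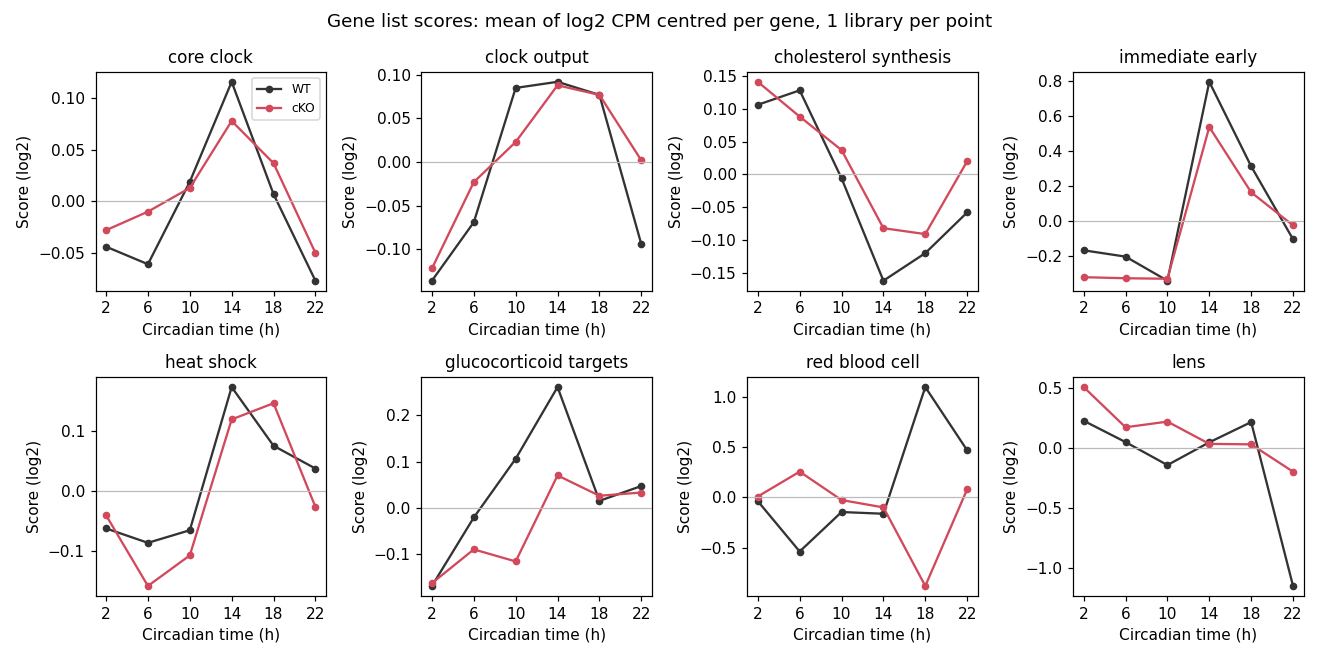
List scores, the mean over a list of log2 CPM centred per gene (vertical axis, log2, scaled per panel), against circadian time in h (horizontal axis) in WT (black) and cKO (red), 1 library per point. The immediate early score was highest at CT14 in both genotypes, the red blood cell score was 1.09 in WT and -0.88 in cKO at CT18, and the lens score was -1.15 in WT at CT22.

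No other list passed Fisher's exact test for shared rhythms, where 3.5% of all tested genes passed. That test takes the members of a list as independent, although all were measured in the same 12 libraries. Its p-values are therefore too small where members move together. Among the lists past it, the correlation that camera estimated ran from -0.028 for clock output to 0.692 for rods. Time was fitted as a factor there, so these values leave out what members share at a time. A low correlation therefore does not show that the Fisher p-value of a list is little affected. Müller glia had 2 of 12 (16.7%, adjusted p = 0.188) past the shared test over all genes and 3 over the list alone, including Abca8a (CT 18.7) and the carbonic anhydrase Car14 (CT 14.3), and ribosomal proteins 3 of 82 (4 over the list alone). Single members passed in the cone (Arr3), bipolar (Grm6, CT 19.3), reactive glia (Stat3, CT 19.4), ciliary body (Slc4a4, CT 10.7), corneal (Krt14, CT 21.4) and vascular (Kdr, CT 6.1) lists. In edgeR's shared test no member passed in the corticosteroid receptor, amacrine and horizontal cell, ganglion cell, pigment epithelium, lens, stroma, muscle, red blood cell, immune, mitochondrially encoded or nuclear oxidative phosphorylation lists, where 0 to 5 members each had an unadjusted p below 0.05, and 2 pigment epithelium genes passed adjusted over the list alone. Exact tests of the list scores over the 720 orders of the times gave none past the adjusted threshold (smallest adjusted p 0.45 in WT and 0.225 in cKO, with 1 and 3 lists at an unadjusted p below 0.05, 0.0167 being the smallest p possible). With 1 cycle and 1 pool per genotype and time, a rhythm cannot be told from a difference between times that would not recur. The count of 523 went to 217 without the CT10 pair, 217 without the CT18 pair, 332 without the CT6 pair and 342 without the CT22 pair, and a test for any difference between times called 292 genes, 228 of them among the 523.

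Within each genotype, 55 genes passed the rhythm test in WT and 23 in cKO, 15 of them in both. The genes past both tests included Irf7 (fitted range 2.66-fold in WT and 3.11-fold in cKO), Nr4a1, Angptl7, Arr3, Drd4, Dbp, Rbm3, the kinase Sik2 (amplitude 0.54 ± 0.07 in WT and 0.58 ± 0.07 in cKO), Pdzph1 and the glutathione transferase Gsta3. With each pair of libraries left out in turn, Irf7 kept both calls in all 6 cases, Nr4a1 its WT call in 4 and its cKO call in 2, and Angptl7 these calls in 1 and 2. The cKO call was kept in 4 of 6 by Arr3, Drd4 and Sik2 and in 2 of 6 by Pdzph1 and Gsta3. In WT the leaders by amplitude further held the matrix genes Ctgf (0.96 ± 0.12, CT 16.0) and Thbs1 (0.80 ± 0.10, CT 16.8), the proliferation marker Mki67 (0.84 ± 0.14, CT 4.2), Hbb-bt (0.94 ± 0.14, CT 18.8), Adh6a (0.75 ± 0.11, CT 21.2), Rad54b (0.69 ± 0.12, CT 18.2), Fmo1 (0.66 ± 0.10, CT 16.6) and Ciart (0.65 ± 0.09, CT 10.4). Their amplitudes in cKO, none past the test, were 0.46 for Ctgf, 0.48 for Thbs1, 0.34 for Mki67, 0.33 for Hbb-bt, 0.09 for Adh6a, 0.59 for Rad54b, 0.61 for Fmo1 and 0.39 for Ciart. Adh6a in WT was at 7.87 to 12.93 CPM at CT2 to CT14. At CT18 and CT22 it was at 17.52 and 20.17 CPM, within the 13.19 to 20.69 of cKO. The chromosome 3 span and Rps13-ps1 were near cKO in the same WT libraries, so a difference between pools cannot be told from a rhythm of Adh6a. With pairs left out in the same way, Ctgf and Thbs1 kept the WT call in all 6 cases, Adh6a in 4, Hbb-bt and Ciart in 3 and Fmo1 in 2, whereas Mki67 and Rad54b lost it in all 6 (adjusted p up to 0.206 and 0.385). Without the WT library of CT18 alone, Ciart kept it and the other 7 lost it, Ctgf (adjusted p = 0.0519) and Thbs1 (0.0683) included. The red blood cell score, of which Hbb-bt is itself a member, was 1.09 in WT at CT18, against -0.54 to 0.47 in the other WT libraries. Another member, Hba-a1, was at 129.57 CPM in WT at CT18 and at 40.95 to 71.41 CPM in the other WT libraries. Rps13 was also called in WT (0.57 ± 0.09, adjusted p = 0.0223), but its counts were high where those of Rps13-ps1 were low, and the sum of both had an amplitude of 0.08 (adjusted p = 0.623). In cKO the leaders further held the sarcomere gene Tcap (0.62 ± 0.09, CT 14.8), Ptprn, a secretory granule protein (0.50 ± 0.08, CT 20.9), Pnp and Psmb5, which kept the cKO call in 2, 3, 4 and 1 of the 6 cases.

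Glucocorticoid targets past the WT test over all genes numbered 4 of 29 (Ddit4, Tsc22d3, Per1 and Fkbp5, the last with an amplitude of 0.40 in WT and 0.09 in cKO), and none passed in cKO in edgeR, where 9 had an unadjusted p below 0.05 and 4 passed adjusted over the list alone, against 9 over the list alone in WT. Of the core clock 5 passed in WT (Per1, Per2, Nr1d2, Dbp and Ciart) and 1 in cKO (Dbp), and 12 and 11 adjusted over the list alone. These counts do not by themselves test a difference between genotypes. Of the 40 genes past the WT test and not the cKO test, 29 had an unadjusted p below 0.05 in cKO. None of the 40 passed the test of the difference, while 17 had an unadjusted p below 0.05 in it, against 2.58% of all genes, although genes picked as past 1 test and not the other are favoured to differ. Fitted on their own libraries, WT gave 24 genes and cKO 69, the opposite order. Counts varied more between WT than between cKO libraries in each range of mean count examined. At mean counts of 100 to 1000 the median ratio of variance to Poisson variance was 2.345 in WT and 1.922 in cKO. At 20 to 100 it was 1.806 and 1.585. With 1 library per genotype and time, this spread cannot be told from differences between times. The model of all 12 libraries fits a common spread, and its part in the WT and cKO counts was not tested. The p-values rest on pooled libraries, not on single mice. The WT count was 86 without the CT2 pair, 16 without the CT6 pair, 28 without the CT10 pair, 13 without the CT22 pair and 15 without the WT library of CT18 alone. The cKO count was 11 without the CT6 pair, 3 without the CT10 pair and 12 without either the CT18 or the CT22 pair.

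The test of the rhythm difference called 2 genes, Pnp and Psmb5. Of the 32 within-time swaps of genotype, the real one included, 8 called as many or more, so this count is no larger than arbitrary labels can give. A haplotype on chromosome 14 that differed between pools could also account for both calls, as set out below. Pnp, purine nucleoside phosphorylase, peaked at CT 3.5 in WT (amplitude 0.34 ± 0.07) and at CT 16.2 in cKO (0.55 ± 0.07, adjusted p of the difference 0.0117). It was at 78.5 CPM in WT and 41.9 CPM in cKO at CT2, and at 55.6 and 89.3 CPM at CT14. Psmb5, a catalytic subunit of the proteasome, peaked at CT 5.0 in WT (0.30 ± 0.06) and CT 15.5 in cKO (0.38 ± 0.06, adjusted p of the difference 0.0319). In WT neither gene passed the rhythm test (adjusted p = 0.0948 for Pnp and 0.0777 for Psmb5), so their WT peaks are fitted values only. Both lie on chromosome 14, starting at positions 50931082 and 54614119 in GENCODE M21 (GRCm38). The 8 named genes next by p, none of which passed, were Hjurp (adjusted p = 0.0938), Hbb-bt (0.211), Ppp1r3e (0.466), Hba-a2 (0.562), Slurp1 (0.946), Hbb-bs and Hba-a1 (0.963 each) and Rpgrip1 (1.00). The 4 haemoglobin genes peaked between CT 18.7 and CT 19.3 in WT and between CT 4.0 and CT 5.4 in cKO, and all 5 tested red blood cell genes passed adjusted over the list alone. Their score at CT18 was 1.09 in WT and -0.88 in cKO. Over the alternatives run, the size of the difference fell as low as 0.426 for Hba-a2, 0.415 for Hbb-bs and 0.395 for Hba-a1. In the main run these sizes were 0.980, 0.937 and 0.981. For Hbb-bt the lowest size was 0.923, against 1.246 in the main run. One corneal gene, Slurp1, and 1 mitochondrially encoded gene also passed adjusted over their lists alone, and no member of any other list did. Across all genes 390 had an unadjusted p below 0.05, where 757 would be expected by chance. This model has no term for what both genotypes share at a time beyond the rhythm. With time as a factor, added after the data were seen, 368 genes had an unadjusted p below 0.05, so the lack of that term does not account for the shortfall. In that model 8 genes passed: Pnp, Psmb5, Hjurp and 5 gene models outside the naming rule, among them Rps13-ps1. In the model without time as a factor, Pnp and Psmb5 both lost their calls without the CT6 or the CT10 pair (0 genes, with 411 and 392 at an unadjusted p below 0.05). Both were also lost without the WT library of CT18 alone. Pnp lost its call without the CT2 pair, and Psmb5 without the CT14 or the CT18 pair. The size of the difference stayed between 0.80 and 0.96 for Pnp and between 0.57 and 0.80 for Psmb5 over all left-out pairs.

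Rhythm amplitude was compared between genotypes over the 523 shared genes. The median log2 ratio of the cKO to the WT amplitude was -0.08, with 302 genes lower in cKO, and it ran from -0.17 without the CT18 pair to 0.01 without the CT6 pair (exact test over the 32 within-time swaps of genotype, two-sided p = 0.375, smallest possible 0.0312). The fitted peak times differed by a median of -0.08 h, and 458 of the 523 genes peaked within 2 h of each other. The shared test favours genes that vary alike in both genotypes. In simulations, none of 100 genes with an amplitude of 0.5 in WT alone passed it, while 56 of the 100 passed the difference test. No simulated gene had a shared rhythm there, so few genes passed and the adjusted threshold was harder to reach than here. In the real data 48 of the 55 WT calls and 21 of the 23 cKO calls passed the shared test. The simulations thus do not show that the 523 genes leave out rhythms stronger in WT. Core clock genes had lower fitted amplitudes in cKO in 15 of 20 cases (median log2 ratio -0.30, exact p = 0.156), for example Per2 (0.44 ± 0.07 in WT and 0.26 ± 0.07 in cKO) and Per3 (0.23 and 0.05). Glucocorticoid targets were lower in 19 of 29 cases (median -0.41, exact p = 0.344), for example Tsc22d3 (0.35 and 0.22) and Ddit4 (0.40 and 0.24).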

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

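The tests on chromosome 14, on the phase of the clock and with time as a factor were chosen after Pnp and Psmb5 had been seen, and the within-time swaps of genotype for the model without it were planned. Of 100 groups of 6 libraries examined for a value far from the others, 5 held such a value, and 5 would be expected by chance, at about 1 in 20.

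In WT at CT22, the date-named entries took 0.1674% of the counts, against 0.1567% to 0.16% in the other WT libraries. These entries were left out of all tests and hold a median of 0.158% of the counts over all libraries (0.1543% to 0.1674%), a signal in data that was not otherwise used. The score of corticosteroid receptors and enzymes in cKO at CT6 was -0.41, against -0.09 to 0.03 in the other cKO libraries. The retinal ganglion cell score in cKO at CT10 was -0.084, against -0.029 to 0. The lens score in WT at CT22 was -1.147, against -0.143 to 0.225. The red blood cell score in cKO at CT18 was -0.881, against -0.101 to 0.254, and the highest score of the same list was that of WT at CT18, at 1.094.

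Pnp and Psmb5 were flagged because the test of the difference between the genotypes' rhythms called them, with sizes of 0.881 and 0.671 on the log2 scale. As many as 2 genes or more were called in 8 of the 32 within-time swaps of genotype, with at most 13 in another split, and with time as a factor 11 of the 32 swaps reached the real 8 genes, with at most 57, so neither count is larger than arbitrary genotype labels can give. A change of the circadian phase of the eye is argued against, since all 20 core clock genes, taken without selection by a rhythm test, differed in peak time by a median of 1 h (at most 4.9 h), against 11.3 h for Pnp and 10.5 h for Psmb5. A haplotype on chromosome 14 that differed between pools could account for both calls: the genes lie 3.7 Mb apart, and 15 of the 134 other tested genes within 5 Mb (11.2%) had an unadjusted p below 0.05, against 2.58% of all genes and at most 7.5% in runs of as many neighbours elsewhere. This was found and tested on the same data, the genotypes of the single mice at this locus were not measured, and an effect of receptor loss on these genes stays open.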

How the results depend on the processing

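The settings named as added in the processing part were chosen after the data were seen. DESeq2 size factors moved no count by over 1.5 times, nor did limma-trend, and Nr3c1 and Etnppl kept their direction and threshold throughout. For the genotype changes of named genes, 140 values stayed on the same side of the threshold, 75 lost it and none changed sign. For their rhythms, a value counted as reversed if the fitted peak, or that of the difference between genotypes, moved by over 6 h. Of these values 452 stayed on the same side, 125 lost it, 8 gained it and none reversed. Only genes past the test in the main run could count as reversed, which leaves out the named genes of the rhythm difference other than Pnp and Psmb5. DESeq2 gave no adjusted p for 11 further values, which were left out. Totals of calls that moved by over 1.5 times are given next. Without the filter on low counts they were 51 for genotype (27 higher, 24 lower), 108 for WT rhythm, 52 for cKO rhythm and 7 for the rhythm difference. With DESeq2 they were 104 for WT rhythm, 68 for cKO rhythm and 5 for the difference. Genotype without the time term gave 3 (1 higher, 2 lower), 6 lower with cosine and sine terms and 4 higher without the genes of the chromosome 3 span, in place of 10 higher and 11 lower. The rhythm difference with time as a factor gave 8. WT libraries alone gave 24 in place of 55, and cKO libraries alone 69 in place of 23. Both fits had fewer samples and 3 residual degrees of freedom, yet the cKO count rose. Without the WT library of CT18, WT rhythm gave 15 and the difference 1, and without that of CT22 WT rhythm gave 22. Any difference between times gave 292 in place of 523. With each pair of libraries left out in turn, which leaves fewer samples, genotype ran from 5 to 26 (0 to 14 higher, 4 to 19 lower), WT rhythm from 13 to 86, cKO rhythm from 3 to 32, the shared test from 217 to 368, the difference from 0 to 4, the amplitude ratio from -0.168 to 0.01 and the gene set test from 9 to 15. The amplitude ratio was -0.295 on core clock genes and -0.413 on glucocorticoid targets, and 0 lists were called by the gene set test with an estimated correlation, in place of 13. List scores gave 0 throughout. Without the filter more genes were tested, yet the estimates of Nr3c1 and Etnppl hardly moved while their adjusted p fell. It was 7.02e-06 in place of 0.0018 for Nr3c1 and 2.11e-07 in place of 0.000629 for Etnppl (edgeR genotype test). More tests alone thus do not account for the higher genotype count. For the changes without the filter, with DESeq2, with the time terms, with each genotype alone and with the test for any difference, the cause was not tested. With 1 pool per genotype and time at 10466253 to 10686868 counts, part of the smaller changes was missed: 64 of 100 simulated genotype changes of 0.3 and 73 of 100 shared rhythms of 0.25 were recovered. The simulated changes were placed in better expressed genes only. Recovery was not split by expression, and at low expression it was not measured.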

Other observations

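The tests of the shared rhythm count and its splits, of the excess of WT over cKO rhythm calls, of the span on chromosome 3 and of Rps13 were chosen after these results had been seen, and the other counts of splits were planned. Beyond the comparisons above, transcripts of pituitary hormones were present at low counts. Gh had 32 to 86 counts in WT and 19 to 33 in cKO. Prl, picked after its values were seen, had 14 to 57 in WT and 11 to 20 in cKO (log2 difference -1.14 ± 0.23 SE, adjusted p = 0.0951, not past the edgeR test). In WT both were highest at CT2 and CT18 (Gh 86 and 86, Prl 57 and 54) and low at CT6 and CT22 (33 and 32, 17 and 14). The pituitary hormone precursor Pomc, picked in the same way, had 36 to 81 counts in WT and 34 to 59 in cKO, so it did not fall alike. Hba-a1 had 1361 counts in WT at CT18, 437 to 779 at the other WT times and 301 in cKO at CT18.

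The counts of calls were set against other splits of the same libraries. For genotype, 1 of 32 within-time swaps gave as many genes as the real 21, the real one itself, with at most 12 in another. For WT rhythm, 2 of 60 orders of the times reached the real 55, with at most 66 in another. For cKO rhythm, 1 of 60 reached 23, the next highest being 21, and for the shared rhythm 1 of 60 reached 523, the next highest being 351. In these 4 cases the real labels thus gave as many calls as, or more than, nearly all other arrangements. The excess of 32 calls in WT over cKO was matched in either direction by 12 of 32 swaps, the highest being 160, and is thus no larger than arbitrary labels could give.

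The 6 calls from Schip1 to Golim4 on chromosome 3 lay in a span of 7.9 Mb with 10 other tested genes. Receptor loss acting on the called genes one by one is argued against since the uncalled genes had 92.4% of the median difference of the called ones (0.327 and 0.354). A linked haplotype or a copy number segment that differed between the genotypes' mice is consistent with that median of 0.327, which lay above 99.99% of 14481 runs of neighbouring genes elsewhere, the middle 95% running from -0.066 to 0.058. The score of the span was -0.356 to -0.119 in WT at CT2 to CT14 but 0.019 at CT18 and -0.008 at CT22, near the 0.088 to 0.275 of cKO, in the same 2 WT libraries where Rps13-ps1 and Rps2-ps10 were low, so background that varies between WT pools stays open for other calls. No test told a haplotype from a copy number change or from an effect of receptor loss on the whole segment, and the strain history is not given.

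Rps13 and its pseudogene Rps13-ps1 moved in opposite directions between libraries. A rhythm or genotype effect on Rps13 is argued against: the summed counts had a WT amplitude of 0.078 against 0.57 for Rps13, and a genotype difference of -0.06 ± 0.043 SE (adjusted p = 0.917 in edgeR). Reads of the same transcript divided differently between the gene and its copy are consistent with a log2 SD of 0.071 for the sum over the 12 libraries, against 0.465 for Rps13 alone and a limit of 0.223 from other ribosomal protein genes. Whether a variant in some mice or the read assignment divided them stays open. Rps2-ps10 had 279 to 524 counts in WT at CT2 to CT14, 81 and 88 at the later times and 73 to 107 in cKO, and was not tested in this way.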
